A study of Rattus norvegicus with 24 samples.

How the data were processed

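RNA from the hypothalamic blocks of 18 rats was measured, 1 array per rat. Per the labels' protocols, blocks were kept in a stabilising solution, total RNA was extracted with a phenol reagent and purified further on an automated instrument, and biotin-labelled cRNA was made from 500 ng of total RNA for a 3' expression array. The values are log2 signals per probe set as deposited by the authors, from 5.59 to 14.93. Per the series design text, the authors normalized control and stress arrays as 1 set and the stress arrays again with the stress plus linalool arrays as another, so that each stress array has 2 columns. The method of summarization and normalization, and any centring, is not given in the sources used here. The scale was read as log2 from the range of the values.

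Column medians were 8.165, 8.159, 8.17, 8.174, 8.19 and 8.18 for controls 1 to 6 and 8.17, 8.161, 8.16, 8.165, 8.167 and 8.157 for stress rats 1 to 6 in the first set. In the second set they were 8.153, 8.147, 8.145, 8.146, 8.149 and 8.134 for the same stress rats and 8.137, 8.14, 8.131, 8.141, 8.136 and 8.142 for linalool rats 1 to 6. The spread between arrays differed between probe sets by orders of magnitude. For 16.5% of genes the SD over the same 6 stress arrays differed over 10-fold between the sets, although their 6 values correlated between the sets with a median r of 0.971 over genes. A log2 difference can thus be strongly understated, and genes with a residual SD under 0.01 are called compressed. An unmoderated t is not changed by a factor per probe set, while limma's moderated t is (prior degrees of freedom 0.379 and 0.397), and differences are also given as multiples of the residual SD. Deviations of a stress array from its group mean correlated between the sets at 0.896 to 0.927, and at most at 0.0564 between different arrays, so the arrays carry the numbers of their labels.

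The file holds 31099 probe sets, of which 57 array controls were left out of the gene tests. Of the other probe sets, 20826 have 1 gene symbol in the platform table, 436 have several and 9780 have none listed there. Symbols were checked by gene identifier against a RefSeq gene table of the assembly GRCr8, used for names only (20758 probe sets matched, 0 symbols changed). The 14217 genes were each represented by the probe set with the highest mean over the 24 columns, and 4525 genes had over 1 probe set. All value columns were used.

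Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no filter and no further normalization), with Benjamini-Hochberg adjustment over the 14217 genes and a threshold of 0.05. The labels describe separate animals, so p-values measure the spread between the arrays of different rats. The design and the alternatives, the naming rule and 31 gene lists were fixed before the data were examined. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, each adjusted over the 31 lists. Lists covered stress and hormone responses, neuropeptides, receptors, immune genes, metabolism and markers of neighbouring tissues and cell types. Control probe sets were fitted together with all others and adjusted over the 57.

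The text names, per comparison, up to 12 genes higher and 12 lower past the threshold with the largest log2 difference among those whose mean in the higher group is at or above the median gene. Within that rule, the use of 4 members for lists with a call and 2 for the others was settled after the data were seen, as was the residual SD of 0.01 that marks compressed genes. It always names 14 stress and activity genes (Crh, Avp, Oxt, Trh, Pomc, Npy, Fos, Nr4a1, Egr1, Sgk1, Fkbp5, Per1, Tsc22d3 and Nr3c1), then the 2 to 4 members with the smallest p of each list with a call or with 2 members past the threshold, up to 10 genes past it in both comparisons, and any list member past it. Tnfaip3 and the other genes of both comparisons follow that rule. The order within a list follows the p of the chosen probe set, and other probe sets going the other way at an unadjusted p under 0.05 are mentioned.

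The procedure was tested on simulated data: 10 sets of arrays drawn from the real genes' means and residual SDs, with 200 of 14217 genes moved. In the stress against control setting limma recovered 20.6% of genes moved by 2 residual SDs, 62.2% at 3, 91.6% at 4 and 100% at 6, with 5.51% false calls. In the linalool setting it recovered 20.8%, 63.0%, 92.0% and 100%, with 5.48% false. A list moved by 1 residual SD was called in all 10 sets of each. The simulated genes varied independently, while the estimated correlation within the real lists was as high as 0.948 (meningeal markers, stress against control). The list result therefore does not show how camera performs on lists whose members vary together. Rank product, which ranks differences of unequal scale, was run on 1 simulated set of each setting with 20 permutations. It made 6 and 1 calls over all genes, and whether these were among the 200 moved genes was not checked.

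Alternatives were a block on the replicate number, filters on dim genes, quantile normalization and median centring, variance trend and robust fits, array weights, other choices of probe set, another threshold or fold, rank product, no moderation, and leaving out each array. The transform for linear values was not needed. Sharing of the stress arrays was simulated 100 times. The relation of the named genes to the thalamic score was tested after the data were seen, with every permutation of the 6 arrays inside each group and adjustment over the 113 genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and plots.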

Results

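Gene expression was measured in the hypothalamus of 18 male Wistar rats aged 7 weeks, an outbred laboratory strain, with 3'-biased oligonucleotide arrays. The rats formed 3 groups of 6: controls, rats held in restraint for 2 h, and rats held in restraint while (R,S)-linalool, a monoterpene alcohol found in lavender oil, evaporated from 20 µL of liquid into the air of a 40 L box. Each array held the RNA of the hypothalamic block of 1 rat. The design gives 2 comparisons, each inside the set of 12 arrays that the authors had normalized together: stress against control, and linalool under stress against stress alone. The same 6 stress rats enter both, and control and linalool arrays were never set against each other. Of the 14217 genes tested, 80.9% in the first set and 81% in the second had a residual SD below 0.01 on the deposited log2 scale (median 0.000153 and 0.000148 among them, against 0.137 and 0.0902 for the other genes), so their differences are strongly compressed. For such genes the difference is given in residual SDs, with a standard error of 0.577 residual SDs for 2 means of 6 arrays. The log2 differences given for the other genes are those of the deposited values, and the number of arrays limits their precision.

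The first comparison asked which hypothalamic transcripts differed after 2 h of restraint. Of 26 genes known to be induced by glucocorticoid hormones, 9 rose after restraint, none fell and 17 did not pass (list adjusted p = 7.07e-15; adjusted p = 0.205 with an estimated correlation). Sgk1, a kinase induced by corticosteroids, rose from a log2 signal of 10.83 ± 0.265 to 12.33 ± 0.372 (mean ± SD, 6 rats each), with an SE of the difference of 0.183 and an adjusted p = 0.0117, and was higher in all 6 stressed rats than in any control. Slc2a1, the glucose transporter of the blood-brain barrier, rose by 0.36 (SE 0.0298, adjusted p = 0.00307), and the transcription factors Klf9 and Bcl6 rose by 0.38 and 0.55 (adjusted p = 0.0123 and 0.0117). Lower transcripts included Trib2, a pseudokinase, which fell from 10.18 ± 0.077 to 9.72 ± 0.0995 (difference -0.46, SE 0.0504, adjusted p = 0.0117), and Kdr, the receptor for vascular endothelial growth factor on endothelial cells (-0.64, SE 0.105, adjusted p = 0.0302).

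In all, 101 genes passed an adjusted p of 0.05 in limma, 69 higher and 32 lower after restraint, of which 59 were not compressed. The 6 stress and 6 control arrays did not overlap for 95 of them, and for 1.86% of all genes, where chance gives 0.22%. Among the genes with the largest log2 differences that rose were Pdk4 (1.25), a kinase that restrains the use of glucose for oxidation, Gpd1 (0.92), the cytosolic glycerol-3-phosphate dehydrogenase, the cell cycle inhibitor Cdkn1a (0.91), Gpatch4 (0.87), the metallothionein Mt2A (0.86), the alkaline ceramidase Acer2 (0.79), the arrestin-domain gene Arrdc2 (0.77), Pex11a (0.67), a peroxisomal membrane protein, Plekhf1 (0.67) and Tnfrsf11a (0.58), the receptor RANK. Genes that fell included Tnfrsf11b (-0.63), which encodes osteoprotegerin, Ier5 (-0.44), the transcription factors Sox2 (-0.40), Nkx2-2 (-0.39) and Sox4 (-0.30), the Notch feedback gene Nrarp (-0.36), Map3k1 (-0.34), the transferrin receptor Tfrc (-0.33), cyclin D1 (Ccnd1, -0.27) and the thyroxine transporter Slco1c1 (-0.25). Adjusted p-values of these 20 genes lay between 0.0117 (Nrarp) and 0.0492 (Ier5 and Slco1c1).

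**Figure D1:**
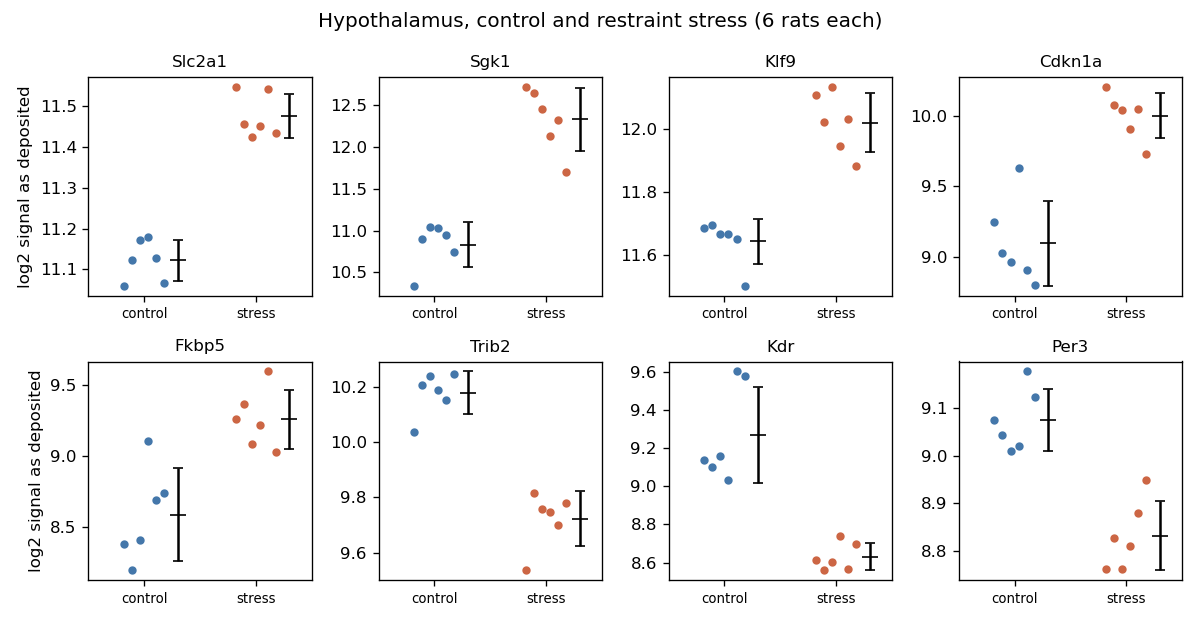
Log2 signal as deposited (y axis) of 8 genes in the 6 control and 6 stress arrays (x axis). Each point is 1 rat, and the bar and whiskers give the mean and SD. The groups do not overlap for Slc2a1, Sgk1, Klf9, Cdkn1a, Trib2, Kdr and Per3, while Fkbp5 (log2 difference 0.67) had an adjusted p of 0.0901.

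Of the 26 measured genes of the glucocorticoid-induced list, 9 rose (Slc2a1, Sgk1, Bcl6, Klf9, Cdkn1a, Arrdc2, Pdk4, Angptl4 and Mt2A), none fell and 17 did not pass. Adjusted over the list alone, 18 rose and 1 fell. The list stood above the other genes by camera with a preset correlation (adjusted p = 7.07e-15), with a median difference of 2.46 residual SDs, and with an estimated correlation its adjusted p = 0.205. By fry, which asks whether the list's genes move 1 way on balance, the adjusted p = 0.00134. Fkbp5 and Tsc22d3, feedback and anti-inflammatory targets of the glucocorticoid receptor, differed by 0.67 and 0.36 without passing (adjusted p = 0.0901 for both), and Per1 by 0.21 (adjusted p = 0.0563). The receptor's own gene Nr3c1 differed by -1.28 residual SDs (adjusted p = 0.309). Of the 17 circadian clock genes, Per3 fell (-0.24, SE 0.0389, adjusted p = 0.0264) and none rose; Bhlhe40 and Dbp differed by -0.42 and -0.15 without passing (adjusted p = 0.17 and 0.33). The clock list stood below the other genes (camera adjusted p = 0.0263; adjusted p = 0.205 with an estimated correlation), and adjusted over the list alone 1 gene rose and 2 fell. Its call ended without control 1 or 3 or stress rat 2 (adjusted p = 0.0519, 0.0528 and 0.0772) and with genes below the median level left out (adjusted p = 0.0994).

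Neuropeptide and immediate early genes gave no call. None of the 37 neuropeptide and hormone genes passed, nor any adjusted over the list alone. Crh, which encodes the hormone that starts the pituitary-adrenal response, differed by -0.03 (SE 0.0245, adjusted p = 0.632), and the log2 differences were -0.48 for Avp, -0.31 for Oxt, -0.17 for Trh and -0.21 for Npy (SE 0.421, 0.642, 0.177 and 0.118; adjusted p = 0.595, 0.841, 0.664 and 0.388). Pomc differed by 0.697 residual SDs (adjusted p = 0.577). The Crh signal (7.82 in controls and 7.80 after restraint) lay below every column median of the set, and 17 of the 37 genes were compressed. How far such signals lie above background was not measured, so these values do not show that the transcripts stayed unchanged. The study's report names neuropeptide and MHC class I genes, so those lists are not independent evidence of a direction. None of the 24 immediate early genes passed, and 1 was lower adjusted over the list alone. Fos, Nr4a1 and Egr1, activity-dependent transcription factors, differed by -0.13, -0.25 and -0.43 (adjusted p = 0.519, 0.304 and 0.228).

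Another 5 lists stood below the other genes by camera with a preset correlation, and none of them did with an estimated correlation. Of 12 endothelial markers, Kdr and Slco1c1 fell (list adjusted p = 0.001; adjusted p = 0.494 with an estimated correlation), 3 fell adjusted over the list alone, and Slco1a4 and Cldn5 differed by -0.35 and -0.11 without passing (adjusted p = 0.101 and 0.288). None of the 44 cytosolic ribosomal protein genes passed over all genes or over the list alone (list adjusted p = 7.21e-10; adjusted p = 0.494 with an estimated correlation), and Rpl24 and Rpl11 differed by -0.08 and -0.09 while Rpl39 and Rpl41 differed by -1.79 and -1.68 residual SDs (adjusted p = 0.167, 0.189, 0.185 and 0.21). None of the 25 MHC class I and peptide-loading genes passed (list adjusted p = 0.0306; adjusted p = 0.679 with an estimated correlation), with Psme1 at -0.16 and Psmb9 at -0.17, and RT1-CE16 and Psmb8 at -1.61 and -1.13 residual SDs (adjusted p = 0.276, 0.365, 0.223 and 0.354). The MHC class I call ended without control 3, 5 or 6 or stress rat 1 or 2 (adjusted p = 0.0769, 0.164, 0.0539, 0.0555 and 0.0772), and the inflammatory call without control 3 or 6 or stress rat 1 or 3 (adjusted p = 0.0834, 0.058, 0.0631 and 0.07). With the mean of a gene's probe sets both had an adjusted p of 0.0537, and MHC class I had 0.0994 with genes below the median level left out. None of the 19 inflammatory genes passed (list adjusted p = 0.0306; adjusted p = 0.494 with an estimated correlation), with Icam1 at -0.35, Vcam1 at -0.24 and Timp1 at -0.46, and Tlr2 at -2.25 residual SDs (adjusted p = 0.192, 0.227, 0.234 and 0.118), and 1 was lower adjusted over the list alone. Of the 14 meninges and fibroblast markers none passed over all genes, and 12 were lower adjusted over the list alone (list adjusted p = 1.22e-07; adjusted p = 0.494 with an estimated correlation). The collagen gene Col1a2 differed by -1.22 (SE 0.456), Aldh1a2 by -1.15, Ogn by -1.13 and Crabp2 by -0.59 (adjusted p = 0.236, 0.234, 0.248 and 0.251).

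These meningeal markers split the control arrays. Their mean score, in residual SDs about the mean of the 12 arrays, was -1.06, -0.602, 0.497, 0.875, 2.27 and 2.12 in controls 1 to 6 and lay between -0.924 and -0.46 in the stress arrays. The first principal component (23.7% of the variance) gave scores of -27.4, 41.2, 15.4, -53.7, -116 and -89 for controls 1 to 6 and of 22 to 58.7 for the stress arrays. Timp1, Icam1 and Psmb9 were also highest in controls 5 and 6. Without controls 4, 5 and 6 the MHC class I and inflammatory lists had camera adjusted p-values of 0.484 and 0.219. With the meningeal score as a covariate MHC class I turned upward (adjusted p = 0.983), and the adjusted p was 0.596 for inflammatory genes, 0.0531 for endothelial markers and 0.578 for the meningeal markers themselves. The score is the mean over those same markers, so the last value follows by construction. It was also lower in the stress arrays on average, so the covariate takes up part of the group difference. Endothelial and ribosomal scores were highest in control 6 (1.49 and 1.58). The other 24 lists had adjusted p-values from 0.0982 to 0.941. They covered immediate early genes, neuropeptides, stress axis receptors, MHC class II, interferon response, chaperones, GABA, glutamate and monoamine systems, oxidative phosphorylation, oligodendrocytes and their precursors, astrocytes, microglia, blood, choroid plexus, ependyma, pituitary, striatum, thalamus, mammillary and preoptic regions, cell cycle and antioxidant genes. By fry the 27 monoamine and acetylcholine genes moved upward on balance (fry adjusted p = 0.0402; camera adjusted p = 0.119; adjusted p = 0.462 with an estimated correlation), with no single member past the threshold and 2 higher adjusted over the list alone.

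The count of 101 genes was not stable: with controls 4, 5 and 6 left out it was 2, with the meningeal score as a covariate 0, with quantile normalization 55, with median centring 62, and it fell to 49, 59, 28 and 40 without control 1, 3, 5 or 6 and to 26, 30, 46 and 28 without stress rat 1, 3, 4 or 5. With the replicate number as a block it was 9, 3 higher and 6 lower. The meningeal score differs between the groups, so as a covariate it also takes up part of the group difference. The count of 0 therefore does not show that these markers account for the calls. Of the 36 called genes named for this comparison, 13 (Sgk1, Slc2a1, Klf9, Bcl6, Acer2, Plekhf1, Trib2, Nrarp, Map3k1, C1h19orf12, Pnpla2, Spsb1 and Tnfaip3) passed in each of the 12 fits that left out 1 array. Without controls 4, 5 and 6 only Kdr of the 36 passed (adjusted p = 0.0381), while Sgk1 and Slc2a1 still differed by 1.57 and 0.359 (adjusted p = 0.116 and 0.0711). Of the 19 other choices of 3 controls to leave out, 13 gave 2 genes or fewer as well. Each of those 13 left out control 5 or 6, which held the highest meningeal scores. The choices that kept both gave 1082, 78, 4 and 250 genes. Leaving out controls 2 and 3 with control 5 or 6 gave 79 and 47. Without controls 4, 5 and 6 the glucocorticoid-induced list still stood above other genes (camera adjusted p = 2.6e-18, and 0.259 with an estimated correlation). Without control 3 the 7 list calls became 4.

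The second comparison asked what differed with the odour under the same restraint. Control probe sets for bacterial RNA, which rats do not make, differed between these groups too, as given below. A processing batch and the odour therefore cannot be told apart, and rose and fell describe the linalool arrays against the stress arrays. With linalool, 49 of 77 oxidative phosphorylation genes rose and 3 fell, and 29 of 44 ribosomal protein genes rose and 2 fell (adjusted p = 0.918 for both lists with an estimated correlation). Of 22 glutamate signalling genes 6 fell and 1 rose (adjusted p = 0.77 with an estimated correlation), a share near the 29.7% of all genes that passed. Ndufa3, a subunit of respiratory complex I, rose from 11.26 ± 0.0538 to 11.67 ± 0.022 (mean ± SD, 6 rats each; difference 0.41, SE 0.0233, adjusted p = 1.96e-05). The ribosomal protein gene Rps3 rose by 0.59 (SE 0.035, adjusted p = 2.64e-05). Syt11, a synaptotagmin of intracellular vesicles, fell from 9.12 ± 0.0353 to 8.51 ± 0.077 (difference -0.61, SE 0.0339, adjusted p = 1.96e-05), and Rgs5, a regulator of G-protein signalling found in pericytes, fell by 0.65 (SE 0.0407, adjusted p = 2.89e-05). For all 4 genes the arrays of the groups did not overlap.

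In all, 4229 of the 14217 genes (29.7%) passed, 2849 higher and 1380 lower with linalool, and 1494 of them were not compressed, 1019 higher and 475 lower. The groups did not overlap for 2012 of them and for 14.2% of all genes, where chance gives 0.22%. That is 67.4% of the calls higher; with quantile normalization 4941 genes passed, 987 higher (20%) and 3954 lower. The genes with the largest differences that rose were Mdm2 (0.85), the ligase that degrades p53, Gpcpd1 (0.77), Dct (0.68), an enzyme of melanin synthesis, the glutathione transferase Gsta1 (0.66), Hdc (0.60), which makes histamine, Rps3, Hopx (0.58), Metrn (0.54), the astrocyte membrane protein Mlc1 (0.54), Mfge8 (0.52), Tmsb15b2 (0.51) and Sec61g (0.50). Those that fell were Rgs7bp (-0.98), the dynamin gene Dnm3 (-0.90), Ptpn3 (-0.70), the nuclear receptor Rora (-0.69), the GABA-A receptor subunit Gabra4 (-0.68), netrin-G1 (Ntng1, -0.67), Sgip1 (-0.65), Rgs5, Cds2 (-0.63), Synpo2 (-0.62), Gatad2b (-0.61) and Syt11. Adjusted p-values of these 24 genes lay between 1.96e-05 (Syt11) and 0.0445 (Synpo2).

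**Figure D2:**
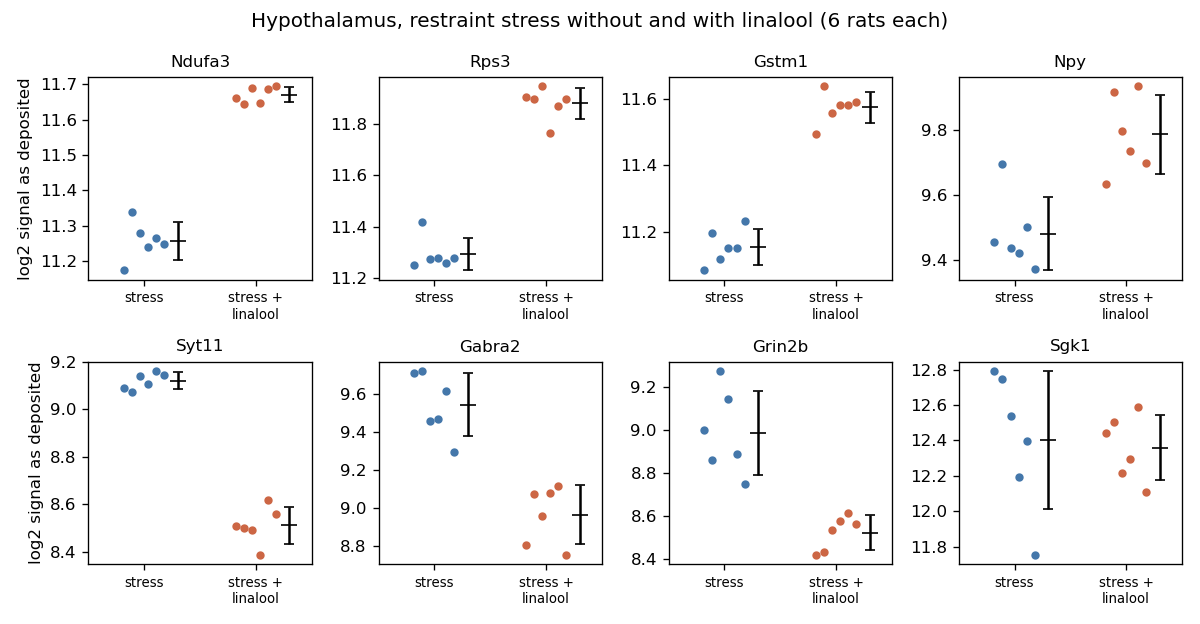
Log2 signal as deposited (y axis) of 8 genes in the 6 stress and 6 stress plus linalool arrays (x axis). Each point is 1 rat, and the bar and whiskers give the mean and SD. Ndufa3, Rps3 and Gstm1 were higher and Syt11, Gabra2 and Grin2b lower in every linalool array than in any stress array, Npy rose with some overlap, and Sgk1 differed by -0.04 (adjusted p = 0.873).

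Of the 77 oxidative phosphorylation genes, 49 rose, 3 fell (Atp5f1d, Cox6b1 and Ndufs7) and 25 did not pass. Uqcrc1 of complex III, Ndufa4 and the cytochrome c oxidase subunit Cox7c rose by 0.36, 0.23 and 0.44 (adjusted p = 9.08e-05, 9.34e-05 and 0.000126). The list had a median difference of 2.35 residual SDs and stood above the other genes (camera adjusted p = 2.95e-09; adjusted p = 0.918 with an estimated correlation; fry adjusted p = 0.000998), and 52 rose and 3 fell adjusted over the list alone. Of the 44 cytosolic ribosomal protein genes, 29 rose, 2 fell (Rpl7a and Rps15a) and 13 did not pass, with Rpl34, Rpl26 and Rps3a rising by 0.27, 0.39 and 0.42 (adjusted p = 4.88e-05, 4.88e-05 and 0.000106). That list had a median of 2.71 residual SDs (camera adjusted p = 7.77e-08; adjusted p = 0.918 with an estimated correlation; fry adjusted p = 0.000819), and 33 rose and 3 fell adjusted over the list alone. Among the 19 antioxidant and xenobiotic genes 6 rose and none fell, led by Gstm1 (0.42, adjusted p = 4.88e-05) and Nqo1 (7.49 residual SDs, adjusted p = 5.24e-05), and 7 rose adjusted over the list alone. Its fry adjusted p was 0.000168 and its camera adjusted p was 0.136 (adjusted p = 0.918 with an estimated correlation). The share of this list that passed was near the 29.7% of all genes that did.

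Of the 22 glutamate signalling genes, 6 fell, 1 rose and 15 did not pass, with Grin2b and Grin2a, NMDA receptor subunits, at -0.46 and -0.51, the metabotropic receptor Grm3 at -0.35 and the AMPA receptor subunit Gria3 at -0.16 (adjusted p = 0.00289, 0.012, 0.00598 and 0.0222). The gene that rose was Gria4, for which 2 other probe sets went the other way, and which was lower with quantile normalization (-0.012, adjusted p = 0.029). The list stood below the other genes (camera adjusted p = 0.00354; adjusted p = 0.77 with an estimated correlation; fry adjusted p = 0.00355), with 7 lower and 1 higher adjusted over the list alone, and with quantile normalization its camera adjusted p was 0.171. Of the 17 GABA signalling genes, Gabra2 (-0.58, adjusted p = 0.00129), Gabra4, Gabrb2 and Gabbr2 fell, none rose and 13 did not pass, also adjusted over the list alone (fry adjusted p = 0.0192; camera adjusted p = 0.0614; adjusted p = 0.902 with an estimated correlation). The share that passed was near the 29.7% of all genes for glutamate and below it for GABA, so these counts alone do not set the 2 lists apart. Of the 9 thalamic markers Synpo2 and Ramp3 (-0.55, adjusted p = 0.0495) fell, while Prkcd and Rgs16 differed by -0.55 and -0.38 without passing (adjusted p = 0.0555 and 0.0503). The thalamic list had a camera adjusted p of 0.0369 (adjusted p = 0.991 with an estimated correlation, 4 lower adjusted over the list alone), with quantile normalization it was 0.427, and it was 0.071 and 0.0546 without stress rat 4 or 6 and 0.0633, 0.0778 and 0.0733 without linalool rat 2, 3 or 5.

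Some of these genes followed the mean score of the thalamic markers from array to array within the groups. Of the 113 called genes named for this comparison, 5 that fell had a positive correlation with it past an adjusted p of 0.05 (exact permutation within groups): Ptpn3, Ntng1 and Gabbr2 (r = 0.956, 0.959 and 0.922; adjusted p = 0.00142, 0.00145 and 0.00427) and the markers Ramp3 and Synpo2, each set against the other markers. Npy and S100a9, which rose, had a negative one (r = -0.903 and -0.705, adjusted p = 0.00427 and 0.0368). Gabra4 and Rora had r = 0.788 and 0.72 without passing (adjusted p = 0.0748 and 0.132). Gabra2, which also fell, went the other way with r = -0.734 without passing (adjusted p = 0.125). With the score as a covariate the difference was -0.179 for Ptpn3, -0.261 for Ntng1, -0.137 for Gabbr2, -0.404 for Gabra4, -0.393 for Rora and 0.161 for Npy (adjusted p = 0.188, 0.0259, 0.161, 0.0457, 0.114 and 0.0202). Syt11 and Rgs5 stayed at -0.609 and -0.652 (adjusted p = 0.000496 and 0.000738), and Gabra2 moved from -0.579 to -0.741 (adjusted p = 0.00159). In that fit 2393 of all genes passed, none of the 113 changed sign, and 27 of the 48 that fell and 41 of those that rose passed. The score differs between the groups too, so the covariate also takes up part of the group difference. The glutamate list then had a camera adjusted p of 0.0126 and a fry adjusted p of 0.0524, and the thalamic list a camera adjusted p of 0.692 (adjusted p = 0.778 and 0.917 with an estimated correlation). The score is the mean over the thalamic markers, so the value for their own list follows by construction.

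Neuropeptide genes moved both ways. Of these genes, as of the MHC class I genes, a smaller share passed than the 29.7% of all genes that did. Npy, an appetite-stimulating peptide, rose by 0.31 (SE 0.0664, adjusted p = 0.00662), Sst by 0.44 (adjusted p = 0.0377) and Nucb2, the precursor of nesfatin-1, by 2.84 residual SDs (adjusted p = 0.00456), while Vgf, a granin-like precursor, fell by 0.37 (adjusted p = 0.00117) and Rln3 by 2.27 residual SDs (adjusted p = 0.0138). The other 32 of the 37 did not pass, and adjusted over the list alone 2 rose and 2 fell. Crh, Avp, Oxt and Trh differed by 0.07, 0.38, 0.29 and -0.01 (adjusted p = 0.72, 0.587, 0.789 and 0.969) and Pomc by 0.437 residual SDs (adjusted p = 0.604). Of the 25 MHC class I and peptide-loading genes 5 rose and 1 fell, also adjusted over the list alone: the proteasome activator Psme1 rose by 0.29 (adjusted p = 0.00264), Psme2, Tapbp, RT1-M3-1 and Pdia3 rose as well, and the chaperone Calr fell by 0.27 (adjusted p = 0.00438). With quantile normalization Psme2 and Tapbp differed by -0.0111 and -0.00148 without passing, and RT1-M3-1 was lower (-0.0108, adjusted p = 0.0166). Neither list is independent evidence, being named in the study's report (camera adjusted p = 0.839 for neuropeptides and 0.637 for MHC class I).

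Of the 26 glucocorticoid-induced genes 4 rose and 1 fell with linalool, and adjusted over the list alone 1 rose. In this list and in the clock and immediate early lists, a smaller share passed than the 29.7% of all genes that did. Tsc22d3 rose by 0.25 (SE 0.0726, adjusted p = 0.0257), Lcn2 by 3.42 residual SDs (adjusted p = 0.00177), and Per1 fell by 0.04 (SE 0.0126, adjusted p = 0.0283). Within the groups Tsc22d3 had r = -0.787 with the thalamic score without passing (exact permutation, adjusted p = 0.0748). It differed by 0.111 with that score as a covariate (adjusted p = 0.228). Sgk1 differed by -0.04 (SE 0.172, adjusted p = 0.873), Fkbp5 by 0.15 (SE 0.129, adjusted p = 0.418) and Nr3c1 by -1.29 residual SDs (adjusted p = 0.117). Of the 17 clock genes, Rora, Per1, Hlf and Npas2 fell and none rose, also over the list alone. None of these passed with the thalamic score as a covariate. Their differences were then -0.393, -0.0517, -0.224 and -0.107 (adjusted p = 0.114, 0.0525, 0.254 and 0.265). Of the 24 immediate early genes Maff (2.31 residual SDs, adjusted p = 0.0123) and Ier2 rose and Jun fell (-1.83 residual SDs, adjusted p = 0.035), with 1 higher and none lower adjusted over the list alone, while Fos, Nr4a1 and Egr1 differed by -0.01, 0.874 residual SDs and -0.20 (adjusted p = 0.957, 0.279 and 0.33).

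Of 14 microglial markers Tyrobp (0.25) and Aif1 (0.17) rose with Itgam. Of 12 oligodendrocyte markers Tspan2 (0.20), Ermn (0.35) and Mobp (0.08) rose and Mag fell (-0.24). Of 12 astrocyte markers Mlc1 rose and the glutamate transporter Slc1a2 fell (-0.43), and of 12 endothelial markers Esam (0.14) and Cldn5 (3.26 residual SDs) rose and Eng fell, but with quantile normalization Cldn5 was lower (-0.0161, adjusted p = 0.0155). Of 9 blood markers 4 rose: Alas2 by 0.36, S100a9 by 2.57 residual SDs, Hbb and Hbe1. Of 14 ependymal markers 3 rose, with Rarres2 at 0.26 and Dynlrb2 at 0.25. Of 11 pituitary markers Chga rose by 0.33 and Gh1 fell by 2.21 residual SDs, and of 13 striatal and telencephalic markers Foxp1 and Camk2a fell by 0.27 and 0.36. Of 18 chaperone genes 6 rose, with Cryab at 0.42 and Hspe1 at 0.21, and of 27 monoamine genes 3 rose and 2 fell, with Hdc higher and Chrm2 lower (-3.11 residual SDs). Ifitm3 (0.35) and Irf1 (1.99 residual SDs) were among the 3 interferon-response genes that rose, and Pcna (0.22) and Aurka (1.95 residual SDs) rose among 11 cell cycle genes. Of 19 inflammatory genes, Vcam1 (0.40), Timp1 (2.89 residual SDs) and Il1r1 (2.38 residual SDs) rose and Tgfb1 (-2.67 residual SDs) and Il1b (-1.94 residual SDs) fell. None of the 14 meninges, 11 choroid plexus and 9 mammillary markers passed, and Avpr1a of the stress axis receptors, Olig2 of the precursor markers, Ciita of the MHC class II genes and Zfhx3 of the preoptic markers were the single calls of their lists. With 29.7% of all genes past the threshold, such counts alone do not set a list apart. The 27 lists without a camera call had adjusted p-values from 0.0614 to 0.985.

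Control probe sets of the array differed between these groups as well. Of the 24 probe sets for bacterial poly-A transcripts, RNAs that labelling kits supply as a spike-in and that rats do not make, 15 were higher and none lower in the linalool than in the stress arrays, and none differed between stress and control arrays. Their mean score lay between -1.84 and 0.086 in the stress arrays and between 0.289 and 1.75 in the linalool arrays. The groups lie on opposite sides of this shift, so for the gene differences above a batch and the odour cannot be told apart.

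**Figure D3:**
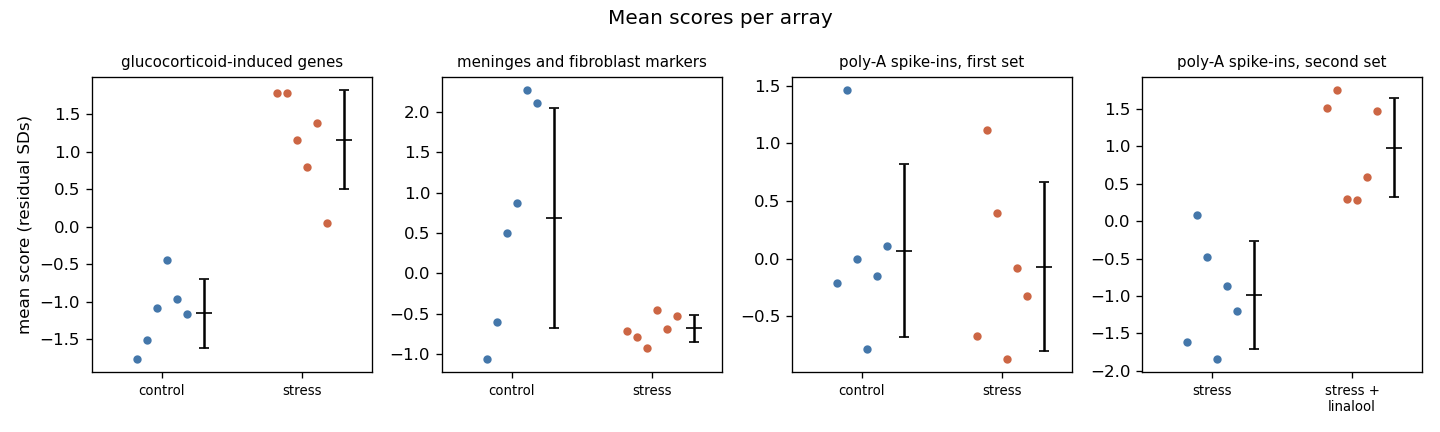
Mean score per array in residual SDs (y axis) for the glucocorticoid-induced genes and the meninges and fibroblast markers in control and stress arrays, and for the poly-A spike-in probe sets in both sets of arrays (x axis). Points are arrays, and the bar and whiskers give mean and SD. Controls 5 and 6 hold the highest meningeal scores (2.27 and 2.12), and all 6 linalool arrays lie above the stress arrays for the spike-ins.

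The count of 4229 ranged from 3548 to 4187 without 1 array and was 1316 with median centring. Among strongly compressed genes, Maff, Lcn2, Nucb2, Irf1, Timp1, Cldn5, S100a9, Aurka, Avpr1a, C1h19orf12, Gria4, Hbe1, Ier2, Ifitm10, Il1r1, Psme2, RT1-M3-1, Spsb1 and Tapbp changed sign with quantile normalization and with median centring. Nqo1 changed sign with the former only, and Itgam and Tnfaip3 with the latter only. Of the 113 called genes named for this comparison, 89 passed in each of the 12 fits without 1 array. Those that did not were Tsc22d3 (adjusted p = 0.0516 without linalool rat 5), Irf1 (without stress rat 1 or linalool rat 1), Ptpn3, Synpo2, Per1, Jun, Dynlrb2, Ramp3, Aurka, Ciita, Gabbr2, Gria4, Hbe1, Hlf, Ier2, Npas2, Pdia3, Psme2, Spsb1, Sst, Tapbp, Tnfrsf11a, Mobp and Il1b.

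The last comparison asked whether the differences seen after restraint went the other way with linalool. Of the 24 genes past the threshold in both comparisons, 11 went in opposite directions, where independent lists of these lengths give 13.1, and 13 in the same direction, where they give 16.9. Opposite were Tnfaip3, an inhibitor of NF-kappaB signalling (-0.43 after restraint and 3.1 residual SDs with linalool; adjusted p = 0.0117 and 0.00312), and Plekha5 (0.21 and -0.36; adjusted p = 0.0227 and 0.00353). The same direction held for the lipase Pnpla2 (0.47 and 0.14; adjusted p = 0.0117 and 0.00602), Tnfrsf11a (0.58 and 0.29; adjusted p = 0.0264 and 0.0254), Spsb1 (0.45 and 1.86 residual SDs; adjusted p = 0.0135 and 0.0324), and, by residual SDs, C1h19orf12 (4.82 and 4.02), Ifitm10 (3.8 and 3.18), Rybp (-3.52 and -2.66), Taf4 (-3.71 and -2.09) and Sox4 (-3.52 and -2.5, with another probe set going the other way with linalool). With quantile normalization C1h19orf12, Ifitm10 and Spsb1 were lower with linalool (-0.0112, -0.0102 and -0.0188; adjusted p = 0.0188, 0.0489 and 0.0091), and with median centring Tnfaip3 differed by -0.00425 (adjusted p = 0.0825). After restraint Taf4 differed by 0.00704 with quantile normalization and 0.0178 with median centring (adjusted p = 0.316 and 0.0795), and Rybp by 0.0107 with the latter (adjusted p = 0.243). Of the 101 genes past the threshold for stress against control, 77 did not pass in the linalool comparison.

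In 100 simulations of unchanged groups that share 6 arrays, the mean count of opposite calls was 0.01 and the highest 1. These groups hold no effect, and a median of 0 genes passed in either simulated comparison, so this count is no measure for 11 opposite genes among 101 and 4229 calls. The covariance of the log2 differences over all genes was -0.000863, where the simulations gave a mean of -0.00081 (from -0.00315 to 0.000199), a difference of -5.32e-05. Pearson's r across genes, which are not independent replicates, was -0.0897 against a simulated mean of -0.363. In residual SDs the covariance was -0.307 against a simulated mean of -0.161, and r was -0.184 against -0.395. With the stress rats split into 3 for each comparison, over all 20 splits, the median covariance of the log2 differences was -3.98e-05 and the median r was -0.0039. In residual SDs the median r over these splits was -0.0753 (from -0.173 to 0.0423). A median of 0 genes passed for stress against control in these splits, so they hold no test of the count of opposite calls.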

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

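Among the tests in this part, the splits of the arrays and the comparisons with lists matched on level were set up before their results were seen; those on spike-ins, compression and meningeal markers were chosen after.

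In 412 groups of 6 values examined, 23 held a value far from the others by Dixon's ratio, where chance gives about 1 in 20 (20.6); the stress arrays are examined in both sets. Oxt had a single low value in each group (ratio 0.855 in controls, rat 2; 0.762 and 0.765 in the stress rats in the 2 sets, rat 3; 0.703 with linalool, rat 1). In controls Trh was low in rat 2 (0.77), Per1 in rat 1 (0.707) and Klf9 in rat 6 (0.765), and in the stress arrays of the first set Taf4 was high in rat 4 (0.713). In the stress arrays of the second set, Rps3 and Ndufs7 were high in rat 2 (0.846 and 0.628), Mfge8 low in rat 1 (0.626), and Dnm3, Sgip1 and Grin2a low in rat 6 (0.716, 0.801 and 0.758). With linalool, rat 1 was low for Mdm2 (0.738) and Crh (0.667) and high for Lcn2 (0.732), Psme1 (0.8) and Ermn (0.649), rat 5 was low for Dct (0.698) and Cds2 (0.682) and high for Pnpla2 (0.678), and rat 4 was low for Cox7c (0.691).

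A signal outside the gene measurements was that of the poly-A spike-in probe sets, 15 of 24 of which were higher in the linalool than in the stress arrays. It bears on the 4229 genes that differed there. The splits speak against chance as their source: 1 of 100 splits of the 12 arrays, the real one, gave as many, and the highest other gave 9. No share below 1 of 100 could be reached with the splits drawn, and they ignore the replicate numbers. Compression of the deposited values is argued against only for the genes without it: 55.2% of them (1494 genes) passed, against 23.8% of the compressed genes. The other 2735 calls were of compressed genes, where this comparison of shares cannot decide. With compressed genes left out 1642 genes passed. With quantile normalization 20% of the calls were higher in place of 67.4%. Labelling or hybridisation of the groups at different times may contribute. It predicts shifts of spike-ins that hold no rat RNA, and 15 of 24 shifted 1 way, against 0 between stress and control. Several of the 24 measure the same bacterial RNA, so they are not independent of each other. The 18 hybridisation controls had medians of -1.46 residual SDs after restraint and -1.25 with linalool, with 1 and 4 past the threshold. A processing difference between control and stress arrays thus stays open too. Stress and linalool arrays lie on opposite sides of the spike-in shift, so a batch between them and the odour cannot be told apart here. An effect of linalool stays open and untested.

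The respiratory chain and ribosomal genes that rose and the glutamate signalling genes that fell with linalool are the second pattern. A trend of the difference with a gene's level is argued against: the medians of the first 2 lists lay at percentile 100 of 10000 random lists matched on level, and that of the glutamate list at percentile 0.03. As a count, however, the 4 lists called by camera were matched or exceeded in 65 of the 100 splits (highest 15), so chance is not excluded for the number of lists. The batch named above could move these genes too (15 of 24 spike-ins), and an effect of the odour stays open.

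The third pattern is the lower level of meningeal markers after restraint. That 2 of the 6 control arrays lay within or below the range of the stress arrays, scores seen before the test was set, speaks only against a fall in every stressed rat below every control, and a fall on average stays open. Meningeal tissue carried along in some control blocks stays open as well: the median correlation of the 14 markers over the 6 control arrays was 0.976 (95th percentile of random lists 0.167), but this follows from scores already seen and holds for whatever made those cells or genes vary. Other differences between those rats were not tested. For the 101 genes the real split alone of 100 gave as many (highest other 1), which speaks against chance over splits that ignore the replicate numbers, while 45 of 100 splits gave 7 or more lists (highest 14), so chance is not excluded for the list count.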

How the results depend on the processing

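The fits without controls 4, 5 and 6, with the meningeal or the thalamic score as a covariate, with compressed genes left out and in residual SDs were chosen after seeing the data. Both scores differ between the groups compared, so these covariates also take up part of the group difference. Except where a construction is named, the cause was not tested. A log2(value + 1) transform was not run, since the values are already log2. How far signals lie above background was not measured here.

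For stress against control (101 genes) the count was 55 with quantile normalization, 62 with median centring, 172 over all probe sets, 237 at a threshold of 0.10, 43 with at least 1.2-fold, 3 by rank product, 2 without controls 4, 5 and 6 and 0 with the meningeal score. It was 26 to 133 leaving out 1 array. In place of 7 lists, 0 passed with an estimated correlation, 2 by fry, 15 with quantile normalization, 4 without genes below the median level, 4 with the meningeal score and 4 to 8 leaving out 1 array. For linalool (4229 genes) the count was 1316 with median centring, 7763 over all probe sets, 546 with at least 1.2-fold, 4 by rank product, 1642 with compressed genes left out, 2393 with the thalamic score and 3548 to 4187 leaving out 1 array. In place of 4 lists, 0 passed with an estimated correlation and 3 to 5 leaving out 1 array. By construction, a fold minimum and rank product pass over compressed genes, and probe sets outnumber genes. Genes opposite in both comparisons (11) numbered 48 at a threshold of 0.10, and 0 with the stress arrays split, where a median of 0 genes passed for stress against control and the count is no test. Their covariance was -3.98e-05 with the split and -0.307 in residual SDs, which is another scale.

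With the replicate number as a block the counts were 9 in place of 101 genes (3 higher and 6 lower in place of 69 and 32, 6 of the 9 among the 101), 3254 in place of 4229 and 4 in place of 11 opposite genes. Deviations of same-numbered arrays correlated at 0.204, 0.0891, 0.0866, 0.122, 0.19 and 0.226 for control and stress and at -0.11 to 0.194 for stress and linalool, and 1 number of 6 in each matched its own best. The numbers were not taken as pairs, since not every correlation was over 0.1 and the labels name no batch shared by number. All those for control and stress were positive, so this cut does not show that the numbers are unrelated. A shared number effect between control and stress arrays stays possible (9 genes with the block).

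Lists were tested again with the block, quantile normalization, genes below the median level left out, the mean of a gene's probe sets, 1 array left out and, after restraint, without controls 4, 5 and 6 and with the meningeal score, and with linalool the thalamic score. There the list calls kept their direction by camera, except MHC class I after restraint with the meningeal score (adjusted p = 0.983, upward), and inflammatory genes were too few to test without dim genes. The glucocorticoid-induced and ribosomal calls after restraint, and the oxidative phosphorylation and ribosomal calls with linalool, also kept their side of the threshold at the preset correlation in these fits. Signs turned as follows, in log2 units. Quantile normalization and median centring shift compressed genes by construction. After restraint they gave 0.00698 and 0.0178 for Nr3c1, 0.0126 and 0.0178 for RT1-CE16, 0.0115 and 0.0178 for Psmb8, 0.00355 and 0.0177 for Tlr2, 0.00705 and 0.0177 for Rpl39, 0.00704 and 0.0178 for Taf4, and centring 0.0178 for Rpl41 and 0.0107 for Rybp. With linalool they gave -0.000343 and -0.00439 for Pomc, -0.00303 and -0.0043 for Nr4a1, -0.000499 and -0.00404 for Maff, -0.000159 and -0.00411 for Lcn2, -0.00603 and -0.00415 for Nucb2, -0.000917 and -0.0042 for Irf1, -0.000808 and -0.00415 for Timp1, -0.0161 and -0.00417 for Cldn5, -4.11e-05 and -0.00402 for S100a9, -0.000426 and -0.00425 for Aurka, -0.000155 and -0.00425 for Avpr1a, -0.0112 and -0.00428 for C1h19orf12, -0.012 and -0.00428 for Gria4, -0.000405 and -0.00414 for Hbe1, -0.00179 and -0.00425 for Ier2, -0.0102 and -0.00415 for Ifitm10, -0.0111 and -0.00434 for Psme2, -0.0108 and -0.00429 for RT1-M3-1, -0.0188 and -0.00426 for Spsb1, -0.00148 and -0.00428 for Tapbp, -0.00152 and -0.00431 for Il1r1, quantile normalization -0.00225 for Nqo1, and centring -0.00417 for Itgam and -0.00425 for Tnfaip3. The mean of its probe sets gave -0.189 for Gria4. Without controls 4, 5 and 6 and with the meningeal score, Oxt was 0.129 and 0.236 and Pomc -3.22e-06 and -1.91e-05, and Psmb9 was 0.0314 with the score. Leaving out 1 array, Oxt was -0.672 to 0.22 after restraint and -0.235 to 0.739 with linalool (above 0 and below 0 only without stress rat 3), and with linalool Trh was -0.096 to 0.125 (above 0 without stress rat 2 or linalool rat 1), Fos -0.0474 to 0.0431 (above 0 without stress rat 1 or 2 or linalool rat 4 or 6) and Sgk1 -0.174 to 0.0341 (above 0 without stress rat 1 or 2 or linalool rat 6). Array weights gave 0.0661 for Trh.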

Other observations

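Tests in this part were all chosen after the data were seen.

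Single lists can be set against the same 100 splits of the arrays. For stress against control, the glucocorticoid-induced genes reached as small a camera p in 2 of 100 splits, the real one included, the monoamine and acetylcholine genes in 3, the cell cycle genes in 6, the meningeal markers in 7, the ribosomal genes in 9, the clock and inflammatory genes in 11 each, the endothelial markers in 15 and the MHC class I genes in 18. For linalool, the ribosomal genes did so in 5, the oxidative phosphorylation, glutamate and antioxidant genes in 7 each, the GABA genes in 11 and the thalamic markers in 28. By fry, the oxidative phosphorylation, ribosomal, glutamate, GABA and antioxidant lists reached so small a p in the real split alone.

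Of the 15 control probe sets of the array for rat genes or other RNAs, housekeeping genes among them, 2 passed as higher and 6 as lower with linalool. Their median difference was -1.43 residual SDs with linalool and 0.497 after restraint, where none passed. The 5' probe set of beta-actin was higher by 0.20 and its middle one by 0.08, those of GAPDH were lower by -0.10 and -0.13, and 5S ribosomal RNA was lower by -0.39. Of the 18 probe sets for hybridisation controls, 4 passed as lower with linalool and 1 as lower after restraint. Past the threshold or not, all 18 had a difference below 0 after restraint (median -1.46 residual SDs) and 17 with linalool (median -1.25), so a shift of these controls was not confined to the linalool comparison.

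The spike-in scores of control and stress arrays with the same number went together: Pearson's r was 0.897 over the 6 numbers (exact permutation p = 0.0111, adjusted p = 0.0222 over 2 such relations) and Spearman's rho 0.829 (exact permutation p = 0.0583). Without numbers 2 and 4, the farthest from the median, r was 0.388, so the relation rests on those arrays. For stress and linalool arrays r was 0.249 (exact permutation p = 0.618) and rho 0.429 (exact permutation p = 0.419), and -0.934 without the same numbers.

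Leaving out 3 control arrays at a time gave from 0 to 1082 genes over the 19 other choices, against 2 without controls 4, 5 and 6. The highest count came without controls 1, 2 and 3, and 13 of the other choices gave 2 genes or fewer. Each of these 13 left out control 5 or 6.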
